A study of Mus musculus with 16 samples.

How the data were processed

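Dural meninges of 12-month-old mice were measured by droplet single-cell RNA sequencing with 3′ polyA capture in 16 libraries, each a pool of 2 animals, from 8 groups (APOE3 or APOE4, control or PLX5622 diet, female or male) with 2 biological replicates each. Per the labels, 5000 cells were loaded per library after magnetic enrichment, for which the protocol names CD45, LYVE-1 and/or CD31 and a sample characteristic CD31 alone. The class shares depend on that enrichment. The tissue was perfused with heparin and actinomycin D, and the strain was C57BL6. The 48 deposited files hold, for each library, a sparse matrix with its barcodes and features. The values are UMI counts per gene and barcode, made by the authors with Cell Ranger 7.1.0 on mm10 before the files were deposited, per the labels' protocols. The submitters' processing notes also name Seurat 5, whose output is not among the files used. Where a library's diet characteristic and its title gave PLX5622 with different end digits, the title was followed.

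Barcodes with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept, and between 10.9% and 35.3% of the barcodes of a library failed the mitochondrial limit. Doublets were scored with Scrublet, and the highest scores were removed at 0.8% per 1000 barcodes. Counts were scaled to 10000 per cell and log-transformed. With scanpy 1.11.5, 2000 variable genes, 50 principal components, 15 neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2) gave 46 clusters over all libraries. Clusters were named from 20 marker lists fixed before the data were examined, for blood and lymphatic endothelial, fibroblast, mural, macrophage, monocyte, dendritic, neutrophil, B, plasma, T, NK and innate lymphoid, mast, erythroid, progenitor, megakaryocyte, osteolineage or chondrocyte, Schwann or neural, arachnoid barrier and microglia cells. The progenitor and megakaryocyte lists had fewer than 4 members measured in each tested class and served only to name clusters.

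Counts were summed per library and class where the class had at least 20 cells, for 9 classes with libraries in all groups and both replicates in at least 6. Macrophage-like sums held 786983 to 10344976 UMIs, endothelial-like 2772365 to 14798294 and fibroblast-like 326733 to 1685114. Quasi-likelihood models were fitted with edgeR 4.0.16 in R 4.3.3, with TMM factors, 1 mean per group and 8 residual degrees of freedom where all libraries were present, after a filter on low counts. The 15 contrasts took the diet within each stratum and over the strata, the genotype within each sex and diet and over the sexes, genotype by sex on control diet, genotype by diet, diet by sex, and male against female on control diet. Adjusted p-values are Benjamini-Hochberg over all genes tested in a class and contrast, with a threshold of 0.05. The SE of a log2 change is its size divided by the root of the F statistic. CPM are counts scaled by edgeR to a common library total with TMM factors, as group mean ± SD. A lone library left in a group by an alternative is assumed to vary like the other groups.

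Class shares were tested with the same models on cell counts per library, adjusted over classes, beside two-sided exact permutation tests within strata. Shares of a single library carry 95% Wilson intervals. The 24 gene lists fixed beforehand covered MHC class I and II, interferon response, NF-kB and cytokines, LXR and lipid efflux, cholesterol biosynthesis, resident dural macrophages, disease-associated microglia type, VEGF with Notch and tip cells, endothelial junctions and transport, extracellular matrix, hypoxia and glycolysis, oxidative phosphorylation, cytosolic ribosome, immediate early, heat shock, glucocorticoid target, circadian clock, oxidative stress, cell cycle, lymphocyte attraction, CSF1 receptor axis, complement and phagocytosis, and sex chromosome genes. Lists with at least 4 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. A class was not tested for its own markers.

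Genes were named by a rule fixed beforehand. For the diet, genotype on control diet, genotype by sex and genotype by diet comparisons of macrophage-like and endothelial-like cells, and diet in fibroblast-like cells, it took up to 12 genes per direction with the largest change among those past the threshold with an average log2 CPM of at least 5. Where fewer than 6 passed, genes up to 6 were named by p as not passing. In the other classes and contrasts it took up to 5 genes with the smallest p, and from each list up to 4 members. The 13 genes Apoe, Csf1r, Mrc1, Lyve1, Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Trem2, Cd74, Pecam1 and Prox1 were read throughout. A marker of another class was named only as such. Hmgcs1 in endothelial-like cells came from its list. A few genes that the rule selects are not reported. Cd74 in E4 PLX5622 males and the block on chromosome 15 were singled out after their values were seen. Positions came from GENCODE vM21 on mm10, in which 32158 of the 32285 features matched by identifier.

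The models were tested on simulated data with 200 changed genes per class. For diet in macrophage-like cells 56.7%, 82.1% and 93.9% of genes changed 1.5, 2 and 4-fold were recovered, with 16 false calls among 184. For genotype in control females these were 43.3%, 80.6% and 81.8%, with 2 false calls among 149. In fibroblast-like cells 11.9% of 1.5-fold and 74.6% of 2-fold diet changes were recovered. A simulated share change of -2 on the log2 scale came back as -2.12.

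Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no low-count filter, a stricter cell filter (500 genes, 1000 UMIs and 5% mitochondrial), doublets kept, Leiden resolutions 0.5 and 2, at least 50 cells, only the groups of a contrast, the replicate number as a block, other denominators and TMM for shares, and each of the 16 libraries left out. A 20% mitochondrial limit, single macrophage clusters, 3 strata without E4 PLX5622 males, females alone, mature and precursor B cells apart, and endothelial-like and other cells without 5 or more UMIs of 12 macrophage markers were added after seeing the data. Neutrophil, monocyte, mast, plasma, erythroid, lymphatic endothelial and Schwann or neural classes had too few cells per library for gene tests, and the unnamed clusters were left out of them because they mix clusters without a common type. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.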

Results

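Single-cell RNA sequencing was performed on the meningeal dura, the outer membrane around the brain, of 12-month-old mice that express APOE3 or APOE4 (E3 and E4 below). The mice received a control diet or a diet with PLX5622, an inhibitor of the macrophage growth factor receptor CSF1R. The 16 libraries fell into 8 groups of genotype, diet and sex with 2 biological replicates each, and every library pooled 2 animals, 32 animals in all. Total unique molecular identifiers (UMIs) in replicates 1 and 2 were 29211478 and 20666374 in E3 control females, 38731633 and 16686822 in E3 control males, 29223196 and 33423439 in E4 control females, and 32185338 and 22155649 in E4 control males. On PLX5622 they were 19529020 and 15443524 in E3 females, 18452305 and 22702811 in E3 males, 33641794 and 68694312 in E4 females, and 33142673 and 19853542 in E4 males. The deposited matrices held 54852 barcodes, from 1721 to 9200 per library, and 41140 cells were kept, from 1149 to 6559 per library. Kept cells had a median of 5916 to 9675 UMIs in 15 libraries and 1329 in E4 PLX5622 female replicate 1.

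The kept cells formed 46 clusters, which marker genes fixed beforehand placed in named classes. Blood endothelial-like cells made up 24.4% of them, macrophage-like cells 17.0%, B cell-like cells 14.3% and T cell-like cells 9.97%. A class led by Gata3, Il1rl1 and Il17rb, which was placed in none of the listed types, held 7.14% and is called Gata3-led here. Gata3 and Il1rl1 are themselves on the NK and innate lymphoid list, so its leading genes do not set it apart from that type. Fibroblast-like cells made up 3.56%, dendritic-like 3.49%, neutrophil-like 2.79%, mural-like 2.67%, NK and innate lymphoid-like 1.66%, monocyte-like 1.19%, mast-like 1.18%, plasma cell-like 0.953%, lymphatic endothelial-like 0.931%, Schwann or neural-like 0.773% and erythroid-like 0.712%, and 7.32% stayed unnamed.

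Apoe (ENSMUSG00000002985), the mouse gene for the lipid carrier of the genotype label, was read first in each group, since the feature list held no human APOE. Whether human transcripts were counted on it is not given in the sources used here, so its levels in E3 and E4 may not be comparable. Levels are in CPM, counts scaled to a common library total, as mean ± SD, here with n = 2. Macrophage-like cells of control mice had 16580 ± 2768 CPM in E3 females, 16670 ± 1154 in E3 males, 16380 ± 448 in E4 females and 15410 ± 581 in E4 males. The E4 against E3 difference was -0.02 on the log2 scale (SE 0.15) in females and -0.11 (SE 0.15) in males, and neither passed. On PLX5622 macrophage-like Apoe stood at 12750 ± 606, 13270 ± 1946, 9679 ± 69.04 and 9140 ± 414 CPM in E3 females, E3 males, E4 females and E4 males. Over the sexes it was lower in E4 on that diet (log2 change -0.47, SE 0.11, adjusted p = 0.042), while the genotype by diet difference did not pass (-0.40, SE 0.15, adjusted p = 0.54). Fibroblast-like cells of the same control groups had 3940 ± 171, 3912 ± 1208, 4748 ± 116 and 3964 ± 134 CPM of Apoe, and endothelial-like cells 1264 ± 122, 1313 ± 544, 1125 ± 231 and 997 ± 11.4.

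The first comparison asked which cells the CSF1R inhibitor removed from the dura. Macrophage-like cells made up 27.8% ± 8.30 of the kept cells on control diet and 8.26% ± 2.18 on PLX5622 (SD, n = 8 libraries each), 3.36-fold lower. Every PLX5622 library lay below every control library. The highest on PLX5622 was 10.6% (95% Wilson interval 8.97 to 12.5) and the lowest on control diet 19.1% (17.7 to 20.5), intervals that cover counting error alone. All shares are those of a suspension enriched for chosen surface markers. The log2 change over the 4 genotype and sex strata was -1.75 (SE 0.17, adjusted p = 2.2e-09), and -1.53 in E3 females, -1.97 in E3 males, -1.96 in E4 females and -1.54 in E4 males. A two-sided exact permutation test gave p = 0.0015, the smallest its 1296 rearrangements allow. Within the macrophage-like class the cluster led by Cd209f, F13a1, Cd163 and Mrc1, genes of resident border macrophages, held 50.6% to 66.6% of cells in the control group means and 32.0% to 40.3% in the PLX5622 group means. Its share of all cells changed by -2.44 on the log2 scale (SE 0.21, adjusted p = 4.8e-06). The cluster led by Spp1 and Mmp12 changed by -1.12 (SE 0.33, adjusted p = 0.049), and the one led by Cxcl9 and H2-Eb1, genes of interferon response and antigen presentation, by -1.18 (SE 0.22, adjusted p = 0.0034).

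**Figure D1:**
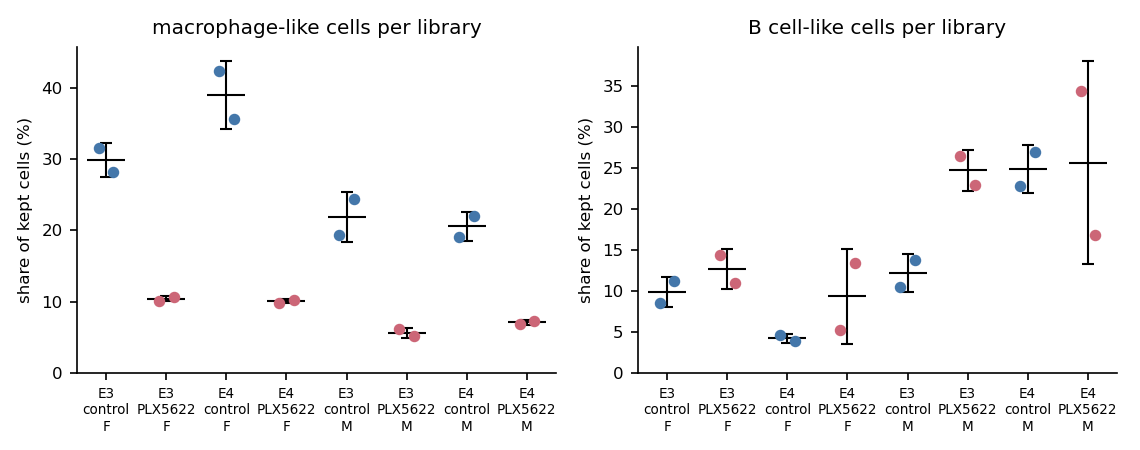
Macrophage-like (left) and B cell-like cells (right) in percent of the kept cells of each library, 1 point per library in 8 groups (blue on control diet, red on PLX5622), with lines for the mean and bars for the SD of 2 libraries. Macrophage-like shares lie between 19.1% and 42.4% on control diet and between 5.10% and 10.6% on PLX5622.

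On PLX5622 2 other classes took a larger share in the mean of the strata, though not in each. B cell-like cells rose from 12.8% ± 8.24 to 18.1% ± 9.34 (log2 change 0.65, SE 0.21, adjusted p = 0.026, exact permutation p = 0.032). Gata3-led cells rose from 5.94% ± 1.54 to 9.02% ± 3.52 (0.57, SE 0.18, adjusted p = 0.026, exact permutation p = 0.015). Neither permutation p passed once adjusted. Among cells other than macrophage-like neither rise passed (B cell-like 0.29, adjusted p = 0.44, and Gata3-led 0.22, adjusted p = 0.55). Loss of macrophages from the total thus accounts for part of both. In E4 males B cell-like cells were at 24.8% and 25.6% on the 2 diets (0.05, SE 0.41), and in E4 females Gata3-led cells at 7.598% and 7.667% (0.01, SE 0.36). Neutrophil-like and erythroid-like cells went opposite ways in females of the 2 genotypes. In E3 females neutrophil-like cells fell by 1.93 on the log2 scale (SE 0.61, adjusted p = 0.033) and erythroid-like cells by 2.14 (SE 0.77, adjusted p = 0.033). T cell-like (1.04, SE 0.37), Gata3-led (1.09, SE 0.37) and mural-like cells (1.18, SE 0.46) took larger shares. In E4 females neutrophil-like (2.75, SE 0.53, adjusted p = 1.6e-04), erythroid-like (2.66, SE 0.60), plasma cell-like (2.11, SE 0.49), B cell-like (1.16, SE 0.43) and unnamed cells (1.23, SE 0.40) rose. These rises rest on PLX5622 libraries with 5688 and 6559 kept cells for 5000 loaded, so diet and preparation cannot be told apart. With macrophage-like cells left out of the total, the T cell-like, Gata3-led and mural-like changes of E3 females (adjusted p = 0.17 each) and the B cell-like (0.30) and unnamed (0.23) changes of E4 females did not pass. The neutrophil genotype by diet difference passed as a mean of the sexes (2.30, SE 0.53, adjusted p = 0.0035) that females carried, since the diet changes of males were 0.38 (SE 0.49) in E3 and 0.30 (SE 0.49) in E4. That of erythroid-like cells did not (0.91, SE 0.70, adjusted p = 0.51). Marrow-type clusters went from 1.26% and 1.96% to 6.56% and 9.79% in E4 and from 5.61% and 6.21% to 2.66% and 3.48% in E3 females. They hold erythroid-like cells and neutrophil and B cell precursors already counted above. The E3 female calls, macrophage-like cells included, each ended without E3 control female replicate 1, and the mural-like change was 0.15 without E3 PLX5622 female replicate 2. The B cell-like rise of E4 females was 0.33 without E4 PLX5622 female replicate 2 and the unnamed one 0.52 without replicate 1. The B cell-like and Gata3-led calls over strata ended without any of 10 and 9 single libraries. An exact permutation within 1 stratum, with 6 rearrangements, cannot go below 0.333.

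In the macrophage-like cells that remained, 1806 of 13086 tested genes passed by diet, 906 higher and 900 lower. Genes of the resident program fell most clearly. Pf4 (platelet factor 4, a marker of border macrophages) went from 2298 ± 364 to 813.5 ± 103 CPM (log2 change -1.49, SE 0.08, adjusted p = 5.9e-10), lower in all 8 PLX5622 libraries than in any control library. The same held for Mrc1 (CD206; -0.66, SE 0.07), for the lectin Cd209f (-1.47, SE 0.16), for the eosinophil attractant Ccl24 (-1.64, SE 0.15) and for Lyve1 (-2.07, SE 0.25, 102 ± 20.9 to 27.1 ± 15.4 CPM), which is also a lymphatic endothelial marker. The chemokine receptor Ccr1 had the largest named fall, from 97.8 ± 14.2 to 13.2 ± 5.53 CPM (-2.89, SE 0.22, adjusted p = 1.4e-05). Ccnd2 (cyclin D2; -1.82, SE 0.12), Gm31243 (-1.61, SE 0.13), Etv5 (-1.42, SE 0.18), Serpinf1 (-1.41, SE 0.09), Ccl7 (-1.38, SE 0.15) and the neutrophil marker Mmp9 (-2.33, SE 0.31) fell as well. Csf1r, which encodes the drug's target, fell by 0.23 (SE 0.06, adjusted p = 0.014) from 1514 ± 106 to 1290 ± 102 CPM, and Apoe by 0.56 (SE 0.07, adjusted p = 4.3e-05). Trem2, a lipid receptor of macrophages, was at -0.03 (SE 0.07) and did not pass.

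Higher in the remaining macrophage-like cells was Cxcr4 (the CXCL12 receptor), which rose from 21.5 ± 4.09 to 71.8 ± 11.6 CPM (log2 change 1.75, SE 0.10, adjusted p = 1.7e-09), higher in 8 of 8 PLX5622 libraries than in any control library. St18 (1.49, SE 0.10), Slamf7 (1.37, SE 0.10, 64.2 ± 13.9 to 167 ± 37.4 CPM) and Phlpp1 (1.04, SE 0.14) rose in the same complete way. Lgals3, the galectin of activated phagocytes, rose from 235 ± 69.9 to 539 ± 188 CPM (1.14, SE 0.21). Sirpb1a (1.48, SE 0.14), Grap2 (1.44, SE 0.19), Coro2a (1.013, SE 0.18), Acp5 (1.012, SE 0.19), Atp8b4 (1.00, SE 0.17) and the ubiquitin-like Isg15 (0.99, SE 0.20) rose with overlapping libraries. Cd74, the invariant chain of MHC class II, rose by 0.31 (SE 0.09), and the endothelial marker Pecam1 by 1.12 (SE 0.21). By stratum 211 genes passed in E3 females, 112 in E3 males, 603 in E4 females and 207 in E4 males. These fell to 32 without E3 PLX5622 female replicate 2, 10 without E3 control male replicate 2, 177 without E4 PLX5622 female replicate 2 and 37 without E4 PLX5622 male replicate 1. Pf4 led in both E3 strata (-1.55 and -1.65), Cxcr4 in E4 females (2.04) and Chp2 in E4 males (-1.71), and St18 rose in both male strata (2.03 and 2.08). AY036118 (-1.68, SE 0.44, adjusted p = 0.041) lost its call when any of 13 single libraries was left out, and in the Cd209f cluster alone Grap2 and Coro2a changed sign, without passing, to -0.58 and -0.36.

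**Figure D2:**
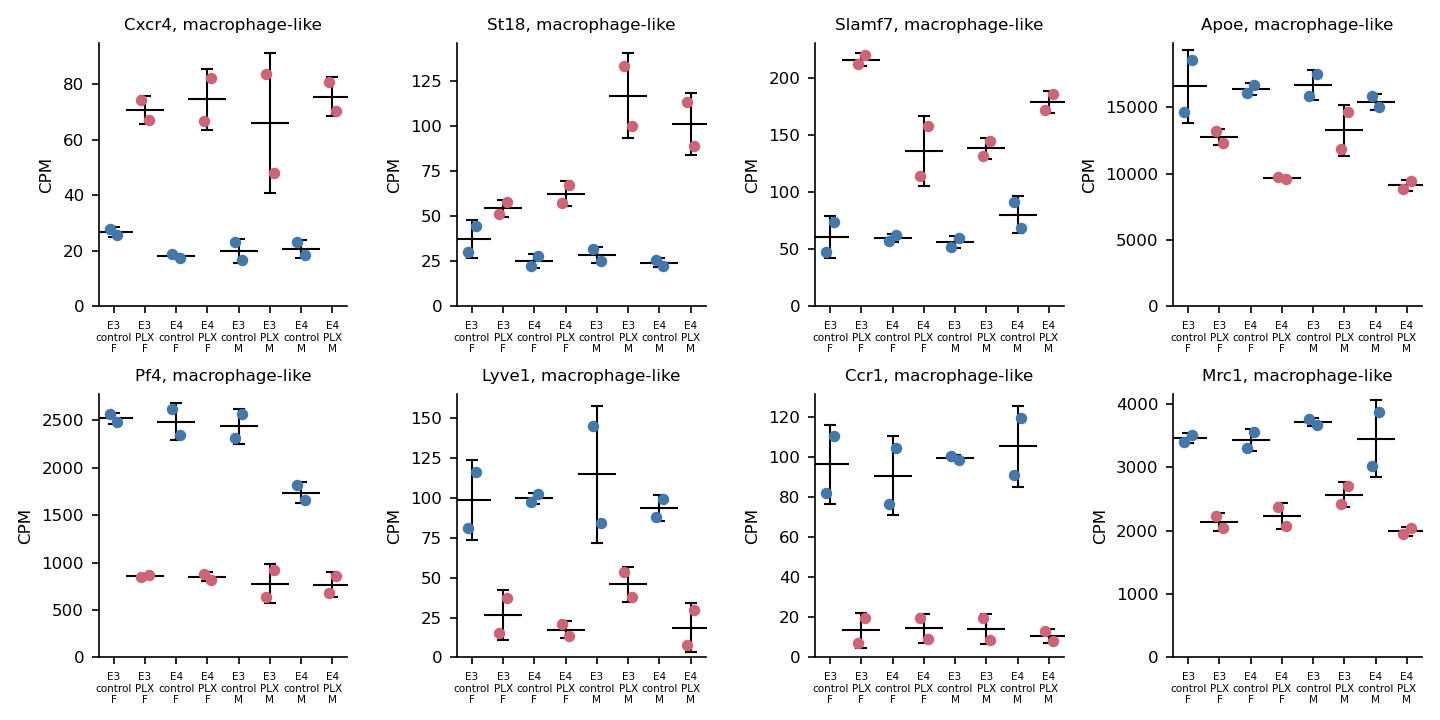
CPM of 8 genes in macrophage-like cells, 1 point per library in 8 groups (blue on control diet, red on PLX5622), with lines for the mean and bars for the SD of 2 libraries. Pf4 lies between 1661 and 2623 CPM on control diet and between 633.5 and 922.0 on PLX5622, and Cxcr4 between 16.9 and 28.1 and between 48.3 and 84.0.

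The resident dural macrophage list fell in these cells. Of 17 measured members 14 fell, 14 also when adjusted over the list alone, with Pf4, Mrc1, Mgl2 (-0.81, SE 0.09) and Folr2 (-0.91, SE 0.10) leading (adjusted p = 3.6e-32, and adjusted p = 0.0029 with an estimated correlation). It was the only list whose call held with that correlation. The Cd209f cluster also held less of the class on PLX5622, and the lists were not tested by cluster. Within that cluster Pf4 (-1.17), Cd209f (-1.17) and Lyve1 (-1.63) still fell and Cxcr4 (1.90) rose, while St18 (0.30), Acp5 (0.38), Atp8b4 (0.42) and Isg15 (0.42) did not pass (adjusted p from 0.084 to 0.69). Of 23 cell cycle genes 8 fell and none rose (10 adjusted over the list alone), among them Cenpf (-1.37), Ube2c (-2.73) and Cdk1 (-1.01) (adjusted p = 0.35 with an estimated correlation). Microglia markers fell, 5 of 6 (6 adjusted over the list alone), with P2ry12 (-0.69) and Cx3cr1 (-0.48) (adjusted p = 0.084 with an estimated correlation). Of 23 complement and phagocytosis genes 11 fell, such as Itgam (-0.58) and Msr1 (-0.71), and 3 rose (16 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation). Interferon response genes rose, 6 of 25 against 1 that fell (12 adjusted over the list alone), with Usp18 (0.64), Irf7 (0.76), Isg15 and Ifit2 (0.97) (adjusted p = 0.60 with an estimated correlation). MHC class I genes rose, 6 of 16 (8 adjusted over the list alone), with H2-T22 (0.47), H2-K1 (0.35), H2-Q7 (0.68) and H2-D1 (0.28) (adjusted p = 0.59 with an estimated correlation). Of 10 MHC class II genes 2 rose, Ciita (0.61) and Cd74 (4 adjusted over the list alone, adjusted p = 0.68 with an estimated correlation). Oxidative stress genes were called upward with 4 that rose, Cat (0.56), Gsr (0.61) and Srxn1 (1.06) among them, and 3 that fell (10 adjusted over the list alone, adjusted p = 0.33 with an estimated correlation).

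Further lists were called in macrophage-like cells and lost with an estimated correlation. Oxidative phosphorylation genes were called downward with 4 of 35 that fell, led by Uqcrb (-0.28; adjusted p = 0.68 with an estimated correlation), and cytosolic ribosome genes with 3 of 35, led by Rps18 (-0.40; adjusted p = 0.72 with an estimated correlation). VEGF, Notch and tip cell genes were called upward with 3 that rose, Cxcr4, Kdr (1.27) and Nrp2 (0.25), and Nrp1 (-0.20) that fell (adjusted p = 0.33 with an estimated correlation). Markers of other cell types moved beside these groups. T cell markers were called upward with 2 of 8 that rose, Cd4 (0.76) and Cd3d (1.72; adjusted p = 0.35 with an estimated correlation). B cell markers were called upward with Vpreb3 (2.17; adjusted p = 0.59 with an estimated correlation). Blood endothelial markers were called upward with Pecam1 and Kdr up and Egfl7 (-1.07) down (adjusted p = 0.59 with an estimated correlation). Dendritic markers were called downward with Cst3 (-0.45) and Siglech (-0.69; adjusted p = 0.33 with an estimated correlation). The LXR and lipid efflux list was not called (adjusted p = 0.89): Nr1h3 (0.71) and Lipa (0.38) rose, and Apoe and Cd36 (-0.82) fell. Nor was the disease-associated microglia type list (adjusted p = 0.11), in which Ctsd (0.54), Axl (0.38) and Ctsb (0.28) were among 5 that rose and Apoe fell. Not called either were the CSF1 receptor axis (adjusted p = 0.99), the NF-kB and cytokine list (adjusted p = 0.98), with Ccl3 (1.04) up and Ccl7 down, and the immediate early list (adjusted p = 0.59), with Atf3 (0.90) up and Klf2 (-1.06) down. The remaining lists not called were endothelial junction and transport (adjusted p = 0.077), lymphocyte attraction and adhesion (0.11), cholesterol biosynthesis (0.35), circadian clock (0.59), and extracellular matrix, hypoxia and glycolysis, heat shock, glucocorticoid target and sex chromosome genes (0.98 each). The same held for markers of monocyte (0.060), erythroid (0.060), neutrophil (0.063), arachnoid barrier (0.063), NK and innate lymphoid (0.072), fibroblast (0.18), plasma (0.43), mural (0.70), mast (0.88), osteolineage or chondrocyte (0.90) and lymphatic endothelial cells (0.98).

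Blood endothelial-like cells asked how vessels of the dura stood after macrophage loss, and 75 of 13918 genes passed, 9 higher and 66 lower. Rnf152, a lysosomal ubiquitin ligase, rose from 40.6 ± 4.62 to 59.8 ± 5.68 CPM (log2 change 0.56, SE 0.06, adjusted p = 2.1e-04), with every PLX5622 library above every control library. Among sterol genes the sterol regulator Srebf2 rose by 0.33 (SE 0.06) and Hmgcs1, an early enzyme of the pathway, by 0.39 (SE 0.08). The cholesterol exporter Abca1 fell by 0.43 (SE 0.06, 181 ± 24.5 to 135 ± 20.3 CPM). The cholesterol biosynthesis list was called upward, with 3 of 22 that rose and 9 adjusted over the list alone, and the call was lost on the stricter test (adjusted p = 0.077 with an estimated correlation). Btnl9 (0.45, SE 0.08), Ablim3 (0.44, SE 0.08), Sema7a (0.35, SE 0.07) and the anticoagulant receptor Thbd (0.25, SE 0.05) rose, and the linker histone Hist1h1e (-0.63, SE 0.10), Rps18 (-0.30, SE 0.06) and Rpl30 (-0.31, SE 0.06) fell. Over the 3 strata without E4 males Hist1h1e was at -0.27 (adjusted p = 0.62) and Rps18 at -0.20 (adjusted p = 0.50), Abca1, Btnl9, Ablim3, Sema7a, Thbd and Rpl30 did not pass (adjusted p from 0.055 to 0.39), and 40 genes did. Rpl30 was high in E4 control females, at 1978 ± 191 CPM (SD, n = 2) against group means of 1178 to 1468 on that diet, as were its neighbours on chromosome 15. The calls of Ablim3, Rpl30, Sema7a, Thbd and Rps18 ended without any of 8, 11, 12, 13 and 13 single libraries, at an adjusted p of at most 0.15. Most of the fall lay in macrophage genes, with C1qa (-2.59, SE 0.13, 58.2 ± 9.74 to 10.6 ± 6.135 CPM), Lyz2 (-1.79, SE 0.20), Fcer1g (-0.87, SE 0.11) and Csf1r (-2.43, SE 0.23). Of the 66 lower genes 60 (90.9%) were at least 4-fold higher in macrophage-like than in endothelial-like cells, against 6.67% of all tested genes. Without cells that held 5 or more macrophage marker UMIs, 13 genes passed, 4 higher and 9 lower, and Rnf152, Srebf2, Abca1 and Hist1h1e were among them. Btnl9 ended its call without E3 control female replicate 1 (adjusted p = 0.053), E4 control male replicate 1 (0.054) or E4 control male replicate 2 (0.057), and Srebf2 without E4 control male replicate 1 (0.054).

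The lists of endothelial-like cells followed the same split. Macrophage markers fell, 10 of 12 (12 adjusted over the list alone), resident dural macrophage genes 9 of 16 (13), complement genes 6 of 22 (9), microglia markers 4 of 5 (4), CSF1 receptor axis genes 3 of 13 (3) and disease-associated microglia type genes 2 of 14 (7), the bracketed counts adjusted over the list alone. All 6 held with an estimated correlation, at an adjusted p from 1.3e-04 to 0.021. Cytosolic ribosome genes were called downward with 1 that fell and 20 adjusted over the list alone (adjusted p = 0.17 with an estimated correlation). MHC class II genes were called downward with none that fell and 6 adjusted over the list alone (adjusted p = 0.14 with an estimated correlation), and LXR genes with Abca1 (adjusted p = 0.36 with an estimated correlation). VEGF, Notch and tip cell genes (1 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation) and extracellular matrix genes (7 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation) were called upward with no member that rose over all genes. Schwann or neural markers were not called (adjusted p = 0.39).

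Fibroblast-like cells had 20 of 12194 genes past the threshold, all lower on PLX5622. Pf4 led (log2 change -3.78, SE 0.39, adjusted p = 0.0071), from 243 ± 64.9 to 29.4 ± 27.4 CPM, followed by the lymphoid and myeloid genes Bank1 (-3.57), Tbxas1 (-3.14), Cx3cr1 (-3.07), Spi1 (-2.73), Fcgr3 (-2.31), Adap2 (-1.62), Ctsc (-1.52) and Rgs10 (-1.39). Dab2, an endocytic adaptor, fell by 1.02 (SE 0.13), with no overlap between the 8 libraries of each diet, and AY036118 (-1.06) and Cmss1 (-0.81) fell too. The E4 male stratum carried most of the last 2, which were at -0.42 (adjusted p = 0.66) and -0.11 (adjusted p = 0.94) over the other 3 strata, where 8 genes passed. Both calls ended without any of 12 single libraries (adjusted p of at most 0.16). Resident dural macrophage genes (2 of 16 fell, 14 adjusted over the list alone) and macrophage markers (1 of 12, 11 adjusted over the list alone) were called downward, at an adjusted p of 3.7e-04 and 0.0043 with an estimated correlation. Of the 20 genes 18 were at least 4-fold higher in macrophage-like cells, and without cells that held 5 or more macrophage marker UMIs edgeR called 0 genes. With those cells kept DESeq2 called 141, and 951 had an unadjusted p under 0.05. The count fell to 1 without E4 PLX5622 male replicate 1 and rose to 161 without E4 PLX5622 female replicate 1.

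Macrophage transcripts also fell in T cell-like cells, where 31 genes passed by diet (3 higher, 28 lower) and C1qa (-2.20, SE 0.18), C1qb (-2.34, SE 0.21) and Apoe (-1.92, SE 0.14, 134 ± 35.6 to 38.4 ± 18.95 CPM) led. They fell in Gata3-led cells too, where 27 passed (9 higher, 18 lower) with C1qb (-2.64, SE 0.30) and Pf4 (-2.05, SE 0.29) ahead. The T cell-like count was 18 without E3 control female replicate 2, and the Gata3-led count 12 without E3 control female replicate 1 and 55 without E4 control male replicate 2. In NK and innate lymphoid-like cells 3 genes passed: Irf7, a master regulator of interferon genes, rose from 40.6 ± 10.2 to 93.4 ± 42.9 CPM (1.11, SE 0.22, adjusted p = 0.045), and Lyz2 (-1.72) and Zmat4 (-2.44) fell. Of 40 splits of the libraries, the real one included, 4 gave at least as many genes, so chance was not excluded for this count. Their interferon response list was called upward with 1 of 24 that rose and 13 adjusted over the list alone, Usp18, Isg15 and Zbp1 next in rank (adjusted p = 0.013 with an estimated correlation). In T cell-like cells macrophage markers (9 of 11 fell, 11 adjusted over the list alone), resident macrophage genes (8 of 12; 11), complement genes (4 of 13; 8), LXR genes (Apoe and Abca1 of 14; 3), MHC class II genes (1 of 7; 4) and disease-associated microglia type genes (1 of 14; 2) were called downward. All 6 held (adjusted p from 3.0e-04 to 0.012 with an estimated correlation). B cell-like cells had 0 genes past the edgeR threshold (905 at an unadjusted p under 0.05, 28 by DESeq2), mural-like cells 0 (893 and 51) and dendritic-like cells 0 (672 and 2). None of their 8, 9 and 5 called lists held, the lowest being resident macrophage genes in B cell-like cells (adjusted p = 0.052 with an estimated correlation).

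The series title names effects of APOE4 that differ between the sexes, and the control diet gives that comparison without the drug. B cell-like cells made up 9.84% ± 1.86 in E3 females and 4.18% ± 0.531 in E4 females, and 12.1% ± 2.35 in E3 males and 24.8% ± 2.89 in E4 males (SD, n = 2). In E4 females they fell by 1.23 on the log2 scale (SE 0.43, adjusted p = 0.048), and in males the change was 1.04 (SE 0.42, adjusted p = 0.085), which did not pass. Among cells other than macrophage-like the female change did not pass either (-1.02, adjusted p = 0.14). The genotype by sex difference was 2.27 (SE 0.60, adjusted p = 0.0071), with an exact permutation p of 0.056, the smallest its 36 rearrangements allow. Erythroid-like cells had the same shape, -2.07 (SE 0.66) in females, 2.09 (SE 0.67) in males and a difference of 4.16 (SE 0.94, adjusted p = 0.0026). These changes rest on 2 to 23 erythroid-like cells per control library. Neutrophil-like cells fell in E4 females (-1.76, SE 0.55, adjusted p = 0.035), though the female erythroid-like and neutrophil-like changes did not pass with macrophage-like cells left out of the total (adjusted p = 0.064 each), and lymphatic endothelial-like cells fell in E4 males, from 1.39% ± 0.149 to 0.491% ± 0.0602 (-1.46, SE 0.51, adjusted p = 0.048). Macrophage-like shares were 29.9% ± 2.42 and 39.0% ± 4.75 in E3 and E4 females and 21.9% ± 3.56 and 20.5% ± 2.09 in E3 and E4 males, with changes of 0.38 (SE 0.33) and -0.09 (SE 0.34) that did not pass. Leaving out E3 control male replicate 1 or E4 control female replicate 2 ended the B cell-like difference between the sexes. The E4 female B cell-like call ended without any of 10 single libraries. The erythroid-like, neutrophil-like and lymphatic endothelial-like calls ended without any of 10 to 12 single libraries, and the E4 male erythroid-like change was 0.85 without E4 control male replicate 2. Across the 8 control libraries the log2 share of mature B cells, the clusters led by Ms4a1 or Ighd, followed that of 6 marrow-type clusters led by genes such as Rag1, Hbb-bs, Mpo, Camp, Mki67 and Vpreb1. Those led by Rag1, Mki67 or Vpreb1 are precursors within the B cell-like class, with 1562, 583 and 96 cells. The others held 293, 479 and 296 cells. The relation thus sets B cells largely against their own precursors, and a change of the whole B lineage could give it too. Pearson's r was 0.907 (exact permutation p = 0.0042, adjusted 0.0084 over 2 relations) and Spearman's rho 0.786 (exact permutation p = 0.028, adjusted 0.056). Without the 2 libraries farthest from the median r was 0.789. On PLX5622 it was 0.289 (exact permutation p = 0.54; rho 0.524, p = 0.20).

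**Figure D3:**
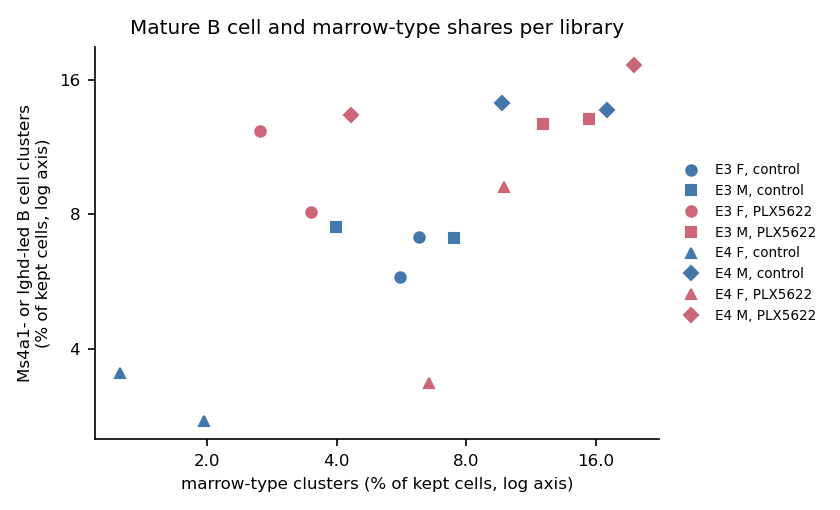
Share of mature B cells against share of marrow-type clusters, in percent of kept cells on log axes, 1 point per library, blue on control diet and red on PLX5622, with shapes for genotype and sex. The 2 E4 control female libraries lie lowest on control diet, with mature B cells at 3.53% and 2.75%, and the 2 E4 control male libraries highest of that diet, at 14.2% and 13.7%. The marrow-type clusters include B cell precursors.

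In macrophage-like cells of control females 6 genes passed between E4 and E3, 3 higher and 3 lower, and the 3 named ones were neighbours on chromosome 15 of mm10. Mtdh (metadherin, ENSMUSG00000022255, 34082694 to 34145624) stood at 374 ± 51.0 CPM in E4 and 217 ± 1.17 in E3 (SD, n = 2; log2 change 0.79, SE 0.12, adjusted p = 0.0092). Cct5, a chaperonin subunit (ENSMUSG00000022234, 31590800 to 31601804), was at 159 ± 6.83 and 97.7 ± 8.64 CPM (0.70, SE 0.12, adjusted p = 0.040). Dap (ENSMUSG00000039168, 31224314 to 31274341) was at 80.7 ± 2.71 and 50.6 ± 3.86 CPM (0.68, SE 0.12, adjusted p = 0.044). Endothelial-like cells of the same mice had 3 genes past the threshold, all higher in E4. These were Mtdh again (0.70, SE 0.09), its neighbour Ankrd33b (0.91, SE 0.14, 182 ± 2.62 against 97.4 ± 15.98 CPM) and the ribonuclease gene Rnaset2b (0.92, SE 0.12, adjusted p = 0.0043, 128 ± 2.08 against 68.3 ± 12.5 CPM). Cct5 reached 0.69 there (SE 0.12, adjusted p = 0.058), with Dynlt1f at -1.30 and Rpl9-ps6 at 1.008, and none of these passed. Mtdh (0.92, SE 0.15) and Cct5 (0.95, SE 0.16) passed in T cell-like cells and Sema5a (1.14, SE 0.16), of the same interval, in mural-like cells. The count in macrophage-like cells was 13 by DESeq2 and ranged from 0 without E4 control female replicate 2 to 15 without E4 control female replicate 1. Mtdh lost its macrophage-like call without E3 control female replicate 1 (adjusted p = 0.25), E3 control female replicate 2 (0.13) or E4 control female replicate 2 (0.19).

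The raised genes stood in a run from Dap to Rpl30 (31224314 to 34443640) whose 6 well-measured members, Dap, March6, Cct5, Cpq, Mtdh and Rpl30, were read in each library as the deviation from the median of the other groups, averaged over 5 cell classes. Their median log2 deviation was 0.661 (SD 0.171) and 0.685 (SD 0.135) in the 2 E4 control female libraries, close to the 0.585 of a 1.5-fold change. The 20 genes on either side were at 0.0731 and -0.0186 in replicate 1 and 0.0494 and -0.000998 in replicate 2. In the other 6 E4 libraries the highest median was 0.0304. The class medians of these genes between E4 and E3 control females ran from 0.355 in B cell-like to 0.701 in T cell-like cells. This region was chosen after its values were seen.

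**Figure D4:**
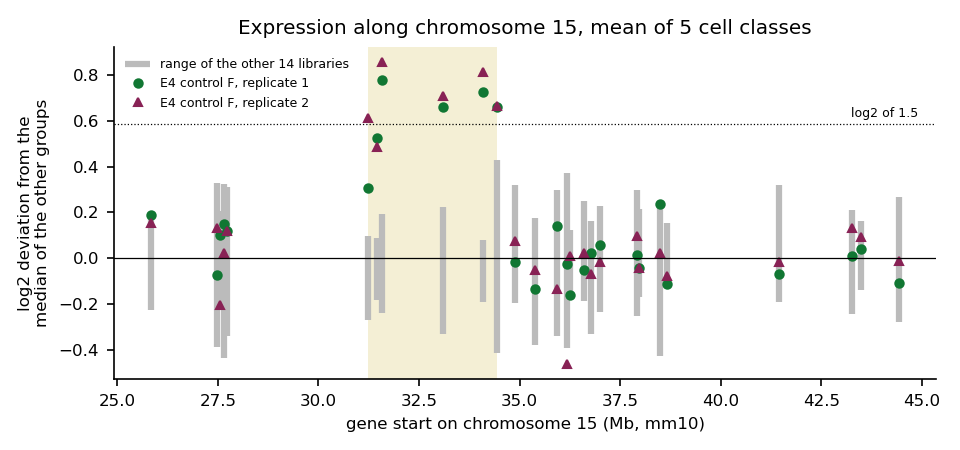
Log2 deviation of each gene from the median of the other groups, as the mean of 5 cell classes, by gene start on chromosome 15 of mm10 in megabases, for the 2 E4 control female libraries (points and triangles) and the range of the other 14 libraries (grey bars), with the block from Dap to Rpl30 shaded and a dotted line at the log2 of 1.5. The block's median is 0.661 and 0.685 in the 2 libraries and the flanks lie near 0.

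In macrophage-like cells of control males 10 genes passed between E4 and E3, 8 higher and 2 lower. Gvin1, an interferon-induced GTPase (ENSMUSG00000045868), rose from 16.7 ± 2.95 to 48.6 ± 3.59 CPM (log2 change 1.51, SE 0.15, adjusted p = 4.6e-05; SD, n = 2). Cebpb, a transcription factor of inflammatory and macrophage genes (ENSMUSG00000056501), fell from 138 ± 22.8 to 51.1 ± 6.38 CPM (-1.43, SE 0.15, adjusted p = 4.6e-05). Both held without each single library. Ipcef1 (1.06, SE 0.20), Zfp810 (0.91, SE 0.17) and AU020206 (0.78, SE 0.14) rose, and the endosomal GTPase Rab21 (-0.81, SE 0.15) fell. Cebpb also fell in T cell-like cells of E4 males (-1.85, SE 0.26) and stood at -1.23 (SE 0.23, adjusted p = 0.28) in their endothelial-like cells. Rab21 fell in T cell-like cells as well (-0.89, SE 0.16). Both sexes together gave 7 genes in macrophage-like cells, led by Cebpb (-0.83, SE 0.10) and Gvin1 (0.83, SE 0.11), and 1 in endothelial-like cells, Rnaset2b (0.68, SE 0.08). They gave 1 in T cell-like cells, Rab21 (-0.69, SE 0.12), and 7 in Gata3-led cells, among them Cebpb (-0.93, SE 0.20) and Rnaset2b (0.66, SE 0.14). Endothelial-like cells of males had 0 genes past the edgeR threshold (999 at an unadjusted p under 0.05, 32 by DESeq2), with Uchl1 (-1.25), Ints9 (0.56), Eid2 (-0.94), Cyp7b1 (0.65) and Rps6ka2 (0.51) ranked first. The male count in macrophage-like cells was 112 by DESeq2 and ranged from 2 without E3 control male replicate 2 to 21 without E3 PLX5622 male replicate 2.

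The sexes differed in the E4 effect for 3 genes of macrophage-like cells. Gvin1 differed by 1.38 (SE 0.21, adjusted p = 0.018) and Cebpb by -1.20 (SE 0.20, adjusted p = 0.045). The haemoglobin gene Hbb-bt, an erythroid marker, differed by 5.47 (SE 0.73, adjusted p = 0.015). In endothelial-like cells edgeR called 0 genes (632 at an unadjusted p under 0.05, 3 by DESeq2), with Cct5 (-0.92, SE 0.17, adjusted p = 0.26) first, Mtdh at -0.61, and Fgf10 (5.70), Sh2d4b (1.63), Rpl9-ps6 (-1.37) and Sfxn5 (1.43) not passing either. Gm11867 (-2.91), Gm21860 (8.04) and Kcnj10 (1.40) ranked next in macrophage-like cells and did not pass. Without E3 control female replicate 1 the macrophage-like count was 0.

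Lists moved weakly by genotype on control diet. In macrophage-like cells of females 11 lists were called. Neutrophil markers (Retnlg, Cxcr2 and S100a9 first) and erythroid markers (Hbb-bt and Hba-a2 first), both downward with 4 and 2 members adjusted over the list alone and none over all genes, stayed at adjusted p = 0.050 with an estimated correlation. Immediate early, extracellular matrix, cholesterol biosynthesis, heat shock, MHC class I and II genes and endothelial markers were called upward, and LXR genes and B cell markers downward, each at an adjusted p from 0.40 to 0.51 with an estimated correlation. In males 11 lists were called. MHC class II genes, with Ciita, H2-DMb2, Cd74 and H2-Aa first, were called upward with none that rose over all genes and 7 adjusted over the list alone (adjusted p = 0.30 with an estimated correlation). Erythroid markers were called upward with 1 that rose (adjusted p = 0.061 with an estimated correlation). Immediate early genes (Ier3, Fosl2, Klf2) and glucocorticoid targets, with 4 and 5 members adjusted over the list alone, and resident dural macrophage genes and mural markers were called downward (adjusted p = 0.27 with an estimated correlation for each). The MHC class II and resident gene calls were not read apart from a shift between clusters. In control males the Cxcl9 and H2-Eb1 cluster went from 18.4% ± 1.07 of macrophage-like cells in E3 to 26.6% ± 1.48 in E4, and the Cd209f cluster from 66.6% ± 1.43 to 50.6% ± 7.33 (SD, n = 2). Oxidative phosphorylation and ribosome genes and neutrophil and endothelial markers were called downward as well (adjusted p from 0.60 to 0.71 with an estimated correlation), and MHC class I genes upward (0.66). Between the sexes 15 lists were called, and only the upward call of erythroid markers held (adjusted p = 0.0069 with an estimated correlation). In endothelial-like cells 10 lists were called in females and 8 in males, and none held. With an estimated correlation the adjusted p ran from 0.29 up in males for immediate early genes (6 downward adjusted over the list alone) and 0.39 in females for mast and B cell markers.

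Fed PLX5622, E4 and E3 mice differed in macrophage-like cells by 192 genes in males (106 higher, 86 lower) and 11 in females (3 higher, 8 lower) with edgeR, and by 305 and 174 with DESeq2. No test compared the sexes on this diet. Cd74 rose in E4 males from 8268 ± 415 to 18340 ± 752 CPM (log2 change 1.15, SE 0.17, adjusted p = 0.0031; SD, n = 2). In all 5 of 10 MHC class II genes rose, Ciita and H2-Aa among them (7 adjusted over the list alone, adjusted p = 0.24 with an estimated correlation). In females Cd74 was at -0.34 (SE 0.17), which did not pass. The make-up of the class shifted the same way, and these changes were not read apart from it. The cluster led by Cxcl9 and H2-Eb1 held 41.3% ± 1.28 of macrophage-like cells in E4 males and 21.4% ± 5.88 in E3 males, and 28.8% ± 15.97 and 42.0% ± 1.47 in E4 and E3 females (SD, n = 2). Resident macrophage genes were called downward in E4 males, with 4 of 17 that fell, Cd163, Gas6, Clec10a and Maf (7 adjusted over the list alone, adjusted p = 0.21 with an estimated correlation). The crystallin gene Crybb1 fell (-3.77, SE 0.46), Chp2 fell (-1.46, SE 0.21), and the mitochondrial calcium channel subunit Mcub (1.27, SE 0.16) and the elongation factor Eef2 (0.99, SE 0.13) rose. In females Klhl13 (3.17, SE 0.52) and Lilra5 (0.73, SE 0.12) rose and Bcl2a1b (-0.88, SE 0.15) fell. Over both sexes 125 genes passed, with Crybb1 (-2.34), Clec4d (-1.46), Rpl7l1 (-0.94) and Adap2os (-0.75) lower and Mcub (0.72) higher. Neutrophil-like (log2 change 2.92, SE 0.58, adjusted p = 5.4e-04), erythroid-like (2.72, SE 0.70), monocyte-like (1.54, SE 0.49), plasma cell-like (1.43, SE 0.51) and unnamed cells (1.41, SE 0.41) took larger shares in E4 than E3 females and T cell-like cells (-0.999, SE 0.36) a smaller one. The mean of the sexes passed for neutrophil-like cells (1.46, SE 0.38), and females carried it, since in males the change was 0.01 (SE 0.49). These female shares rest on the E4 PLX5622 female libraries with 7108 and 9200 barcodes, so genotype and preparation cannot be told apart for them. Without E4 PLX5622 male replicate 1 the macrophage-like count was 31 in males, without E3 PLX5622 female replicate 2 it was 1 in females, and without E4 PLX5622 female replicate 1 the unnamed share change was 0.71.

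A further set of transcripts was lower in E4 than E3 PLX5622 males in several classes. In endothelial-like cells 25 genes passed in males (3 higher, 22 lower), 24 over both sexes and 0 in females (edgeR, with 1505 at an unadjusted p under 0.05 and 36 by DESeq2). There the RNA Gm42418 fell from 56325 ± 8317 to 11162 ± 702.9 CPM (log2 change -2.34, SE 0.20, adjusted p = 4.0e-05). Camk1d (-3.13, SE 0.35), Hist1h1e (-2.06, SE 0.22) and Rpl7l1 (-1.46, SE 0.19) fell. Camk1d fell also in mural-like (-2.82), fibroblast-like (-3.06), T cell-like (-2.14), B cell-like (-1.99) and Gata3-led cells (-2.15), and mt-Atp8 in B cell-like (-2.91), NK and innate lymphoid-like (-3.59) and dendritic-like cells (-3.11). Males had 15 genes past the threshold in fibroblast-like cells (all lower), 40 in B cell-like, 69 in T cell-like, 10 in NK and innate lymphoid-like, 13 in mural-like, 38 in dendritic-like and 60 in Gata3-led cells. Summed over all cells, Gm42418 stood at 6463 ± 1001 CPM in E4 PLX5622 males (n = 2) against group means of 18650 to 38790 elsewhere, AY036118 at 109.5 ± 29.7 against 751.3 to 2390 and Cmss1 at 184.5 ± 16.6 against 1201 to 3292. E4 control male replicate 2 shared part of this, at 11061, 270.9 and 631.5 CPM, while replicate 1 had 26243, 1476 and 1771. E4 PLX5622 female replicate 2 was low in AY036118 (355.5) and Cmss1 (1150) but not in Gm42418 (32647). Replicate 1 of that group had 1147, 3000 and 44234 CPM of the same RNAs. The endothelial-like count in males was 3 without E3 PLX5622 male replicate 1 and 54 without E4 PLX5622 female replicate 2. The labels give no batch, so an effect of E4 in PLX5622 males and a difference in how the libraries were made cannot be told apart, for these genes and for the male counts of all classes. For AY036118 and Cmss1 the same limit applies to the other E4 libraries that were low.

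In the genotype by diet comparison 6 genes passed in macrophage-like cells (1 higher, 5 lower) and 5 in endothelial-like cells (2 higher, 3 lower). In macrophage-like cells 943 genes had an unadjusted p under 0.05 and DESeq2 called 25, while edgeR called 0 with doublets kept, with the stricter cell filter or at Leiden resolution 0.5. Of 60 splits of the libraries, with the real one among them, 5 gave as many macrophage-like genes. In macrophage-like cells the scavenger receptor Colec12 differed by -1.28 (SE 0.20, adjusted p = 0.025), Gvin1 by -0.97 (SE 0.17, adjusted p = 0.045), Adap2os by -0.77 (SE 0.14, adjusted p = 0.045) and the telomere protein Pot1a by 1.005 (SE 0.17, adjusted p = 0.035). In endothelial-like cells Rnaset2b differed by -0.89 (SE 0.12, adjusted p = 0.012), Rab21 by 0.79 (SE 0.11, adjusted p = 0.014), 0610043K17Rik by 0.89 (SE 0.13), Gm11867 by -3.70 (SE 0.57) and Gm10801 by -5.00 (SE 0.83). Ybx3 (0.71, adjusted p = 0.15) did not pass. The Colec12 difference was -1.39 (adjusted p = 0.015) in the Cd209f cluster alone. It was -0.52 in the Cxcl9 and H2-Eb1 cluster and turned to 0.44 in the Spp1 and Mmp12 cluster, and neither passed. Of the 8 lists called in macrophage-like cells and 10 in endothelial-like cells none held, the lowest being neutrophil markers upward (6 adjusted over the list alone, adjusted p = 0.11 with an estimated correlation). In females alone the genotype by diet comparison gave 2 genes in macrophage-like and 1 in endothelial-like cells, and the macrophage-like count was 0 without E3 control female replicate 1 and 13 without E4 control male replicate 2.

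Between control males and females the sex chromosomes led in every class tested. In macrophage-like cells Xist, the RNA that silences an X chromosome, was at 858.8 ± 58.5 CPM in females and 0 in males (SD, n = 4). The Y-linked genes Uty, Ddx3y, Eif2s3y and Kdm5d stood at 117 ± 11.3, 75.9 ± 8.25, 49.3 ± 8.60 and 33.0 ± 5.41 CPM in males and at most 0.720 ± 0.622 in females. All 16 libraries matched their sex label. The sex chromosome list held with an estimated correlation in each of the 9 classes but B cell-like cells. In macrophage-like cells 4 of its 5 genes rose in males and Xist fell (5 adjusted over the list alone, adjusted p = 7.5e-05 with an estimated correlation). Between 5 genes in NK and innate lymphoid-like cells and 41 in macrophage-like cells passed in 8 classes, and 390 did in Gata3-led cells. The macrophage-like count was 15 without E3 control female replicate 1. B cell-like cells took a larger share in males (log2 change 1.44, SE 0.30, adjusted p = 0.0011), while macrophage-like cells were at -0.69 (SE 0.24, adjusted p = 0.062). The B cell-like difference lay mostly in E4 mice, at 4.18% in females and 24.8% in males, against 9.84% and 12.1% in E3. Marrow-type clusters moved with it, at 1.26% and 1.96% in the E4 control female libraries and 9.67% and 17.0% in the male ones. They include precursors of the B cell-like class, so part of this is the same cells. Library quality also parted the sexes, with 26.4% to 35.3% of barcodes over the mitochondrial limit in the 4 control female libraries and 17.8% to 20.5% in the 4 male ones, so sex and preparation cannot be told apart for genes outside the sex chromosomes.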

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

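The tests of marrow-type cells, of macrophage transcripts and of other splits were written first, while the tests of the cell filter, of mature and precursor B cells apart and of the chromosome 15 block were chosen only after the result was seen. The shares and genes here were picked out because the effect of genotype or diet differed between groups by a test of the difference itself, with values as log2 differences. The chromosome 15 block and the macrophage genes of endothelial-like cells were singled out after their values were seen.

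The first pattern is the B cell-like share, where the E4 effect on control diet differed between males and females by 2.27. The cell filter was argued against, since the difference was 2.32 with the mitochondrial limit at 20%. Cells of the skull marrow in the preparation may contribute, since the log2 share of mature B cells followed that of marrow-type clusters over the 8 control libraries (Pearson r 0.907). These clusters include precursors of the B cell-like class itself. A change of the whole B lineage could give the same relation, so it cannot tell this from cells of the marrow. Over the 8 PLX5622 libraries r was 0.289 (exact permutation p = 0.54), so the relation was not general and does not settle the question. Mature B cells alone still differed by 1.97 (adjusted p = 0.017) and precursors alone by 2.88 (adjusted p = 0.024), so both moved the same way. An effect of genotype and sex on marrow output, or on B cells of the dura, stays open and was not tested.

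The next pattern is the block of chromosome 15 from Dap to Rpl30 that was raised in both E4 control female libraries. Shared reads or variants of single genes were argued against, since 87.5% or more of the 8 genes of the interval that were neither called before nor used to place it lay above 0.3 in each of the 2 libraries. In the other libraries at most 37.5% did. Medians there ran from -0.895 (SD 0.652) in E4 control male replicate 2 to 0.237 in E3 control male replicate 2. These genes were read in sums of all cells, so the cell make-up also enters. A segment carried by all E4 mice was argued against as well, since the highest block median among the other 6 E4 libraries was 0.0304. A candidate explanation is an extra copy of the segment in mice of these libraries, for which the same 8 genes had a median of at least 0.642 (SD 0.152) against the 0.585 of a 1.5-fold change. If so, Mtdh, Cct5, Dap and Ankrd33b would mark the animals of this group and not the E4 genotype, and no DNA was there to test it.

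The last pattern is the fall of macrophage genes in endothelial-like cells on PLX5622. Free RNA of macrophages may account for it, since the markers changed in endothelial-like cells by a median of -0.33 (SD 0.605) relative to their change in the sum of all cells. Macrophages or doublets among the endothelial-like cells may do so too, since 69.4% of the marker UMIs of control libraries sat in cells with 5 or more, 268 of 3812 cells. At least 1 marker UMI was seen in 60.5% of control and 27.0% of PLX5622 endothelial-like cells, at median depths of 8475 and 6066 UMIs, against 60.4% and 21.1% of T cell-like cells, which should lack these genes. A change of these genes inside endothelial cells was not tested apart from both.

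Among the shares, the E4 effect on erythroid-like cells differed between the sexes on control diet by 4.16, from 2 to 23 cells per library. The E4 effect on neutrophil-like cells differed between the diets by 2.30 as a mean of the sexes. Females carried it, with diet changes of -1.93 in E3 and 2.75 in E4, against 0.38 and 0.30 in males. The E4 PLX5622 female libraries, with 7108 and 9200 barcodes, enter this difference, so their preparation cannot be told apart from it. In macrophage-like cells the E4 effect differed between the sexes by 1.38 for Gvin1, -1.20 for Cebpb and 5.47 for Hbb-bt. In the same cells it differed between the diets by 1.005 for Pot1a, -1.28 for Colec12, -0.97 for Gvin1 and -0.77 for Adap2os. The diet effect differed between the sexes there by -1.21 for Gramd3. In endothelial-like cells the E4 effect differed between the diets by 0.89 for 0610043K17Rik, 0.79 for Rab21, -0.89 for Rnaset2b, -3.70 for Gm11867 and -5.00 for Gm10801.

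In B cell-like cells the E4 effect on Reln, a lymphatic endothelial marker, differed between the sexes by 2.57 and between the diets by 1.75. In T cell-like cells it differed between the sexes by -1.52 for Camk1d, -10.89 for Cdh20 and 5.31 for the haemoglobin gene Hba-a1. Between the diets it differed there by 1.33 for Rab21, -1.07 for Tspan13, -0.98 for Camk1d and -1.59 for A630014C17Rik. The diet effect differed between the sexes in T cell-like cells by 2.29 for 8030451A03Rik and -0.94 for Camk1d. In NK and innate lymphoid-like cells the E4 effect differed between the diets by -1.53 for Adam19, and in mural-like cells by -1.86 for Camk1d. In Gata3-led cells it did so by -1.02 for Camk1d, -1.07 for Rnaset2b and -2.52 for Gm42726. The diet effect differed between the sexes by -1.06 for Ccnd2 in dendritic-like cells. In Gata3-led cells this difference was -1.014 for Camk1d, -1.40 for Nyap2, 0.88 for Ubb, -1.92 for Lrmda and 0.73 for Eif5a. Summed over all cells, Camk1d stood at 554.7 ± 12.1 CPM in E4 PLX5622 males (SD, n = 2), below the group means of 1413 CPM or more elsewhere.

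Other splits of the libraries were counted for the numbers of genes past the threshold. Chance was excluded for diet in macrophage-like cells (1806 genes, 1 of 100 splits as high, highest other 302), endothelial-like cells (75, 1 of 100, 36) and fibroblast-like cells (20, 1 of 100, 5), and in T cell-like (31, 1 of 40, 17) and Gata3-led cells (27, 1 of 40, 17). It was not excluded for diet in NK and innate lymphoid-like cells (3 genes, 4 of 40 splits as high, highest other 11). For genotype by diet the share of splits as high was under 0.05 in endothelial-like cells (5 genes, 2 of 60, 26) and not in macrophage-like cells (6 genes, 5 of 60, 233). These splits exchange genotype labels, so a genotype difference over both diets also enters them. Chance was therefore not excluded for either genotype by diet count. The split with 26 and 233 genes, several times the real counts, exchanged E4 and E3 in all 8 PLX5622 libraries and in no control library. This turns the comparison into E4 against E3 over both diets, so it points to a difference between the E4 and E3 libraries over both diets. The E4 PLX5622 male libraries were not left out of it, so genotype and the making of those libraries cannot be told apart there.

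For the comparisons with 18 splits the splits are too few for a share under 0.05. For genotype on control diet over the sexes the real count and the highest other were 7 and 47 in macrophage-like and 1 and 0 in endothelial-like cells. For genotype on PLX5622 they were 125 and 110, and 24 and 26. For male against female they were 41 and 3 in macrophage-like, 19 and 2 in endothelial-like, 7 and 1 in fibroblast-like, 9 and 1 in B cell-like, 12 and 3 in T cell-like, 5 and 6 in NK and innate lymphoid-like, 7 and 2 in mural-like, 8 and 1 in dendritic-like and 390 and 5 in Gata3-led cells.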

How the results depend on the processing

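The 20% mitochondrial limit, the single macrophage clusters, the 3 strata, females alone and the cells without macrophage markers were tests chosen only after the result was seen, and the others were fixed before the data were examined. The lower macrophage-like share on PLX5622, as the mean over strata, kept its call under each alternative tried. Within E3 females it ended without E3 control female replicate 1, and within each stratum with the exact permutation test, which cannot pass there. Of the 91 named genes, all were called alike with RLE factors, 82 with a replicate block and 9 weaker, 78 with DESeq2 (9 stronger, 1 weaker) and 65 with the stricter cell filter (14 weaker). Of the 137 called list results 16 kept their call with an estimated correlation and 121 lost it, and 25 and 112 did so with fry. Replicate numbers did not pair the libraries, with correlations between groups from -0.433 to 0.276, and 33 of 34 share results kept their call with a replicate block. Fibroblast-like cells could not be tested with the stricter cell filter or at least 50 cells, where too few libraries were left. The cause was not tested for any change below unless the alternative itself gives it, as where fewer cells or libraries are used.

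For genes past the threshold, macrophage-like, diet, mean of strata, the count of 1806 became 330 in cluster 11 alone and 46 in cluster 5 alone, which hold fewer cells. Without single libraries the count ranged from 1187 (E3 PLX5622 male replicate 1) to 1936 (E4 control male replicate 2). For diet in endothelial-like cells 75 became 459 with no low-count filter, 141 with doublets kept, 13 without cells with 5 macrophage marker UMIs and 40 over 3 strata, and ranged from 44 (without E4 control male replicate 1) to 114 (without E4 PLX5622 female replicate 1). For diet in fibroblast-like cells 20 became 141 with DESeq2, 579 with no low-count filter, 57 with doublets kept, 5 at Leiden resolution 0.5, 77 at 20% mitochondrial, 0 by edgeR without macrophage marker cells and 8 over 3 strata, and ranged from 1 (without E4 PLX5622 male replicate 1) to 161 (without E4 PLX5622 female replicate 1).

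For genotype in control females 6 genes in macrophage-like cells became 13 with DESeq2, 60 with no low-count filter, 23 with only the groups of the contrast, 2 with the stricter cell filter, 3 in cluster 11 alone and 0 in cluster 5 alone, and ranged from 0 (without E4 control female replicate 2) to 15 (without E4 control female replicate 1). In males 10 became 112, 249, 36 and 5 under the first 4 of these, 3 at Leiden resolution 0.5, and 6, 3 and 0 in clusters 0, 11 and 5 alone, and ranged from 2 (without E3 control male replicate 2) to 21 (without E3 PLX5622 male replicate 2). For genotype by sex 3 became 11, 90, 13 and 1 under the same 4, 0 at Leiden resolution 0.5 and 0 in cluster 5 alone, and ranged from 0 (without E3 control female replicate 1) to 6 (without E4 control female replicate 1). For genotype by diet 6 became 25 with DESeq2, 96 with no low-count filter, 0 with doublets kept, with the stricter cell filter, at Leiden resolution 0.5 and in clusters 11 and 5 alone, 3 at Leiden resolution 2 and 2 in females alone, and ranged from 0 (without E3 control female replicate 1) to 13 (without E4 control male replicate 2).

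In endothelial-like cells of control females 3 genes became 12 with DESeq2, 203 with no low-count filter, 0 with only the groups of the contrast, 5 with doublets kept and 5 at Leiden resolution 0.5, and ranged from 0 (without E3 control female replicate 1) to 7 (without E4 PLX5622 female replicate 1). In males 0 became 32 with DESeq2 and 289 with no low-count filter, and ranged from 0 to 3 (without E3 control male replicate 2). For genotype by sex 0 became 3 and 169, and ranged from 0 to 4 (without E4 control female replicate 1). For genotype by diet 5 became 25 and 324, and 1 in females alone, and ranged from 0 (without E3 control male replicate 1) to 10 (without E4 control male replicate 2).

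In cluster 0 alone the diet changes of Grap2 and Coro2a reversed to -0.58 and -0.36 in macrophage-like cells. Without macrophage marker cells Rgs10 reversed to 0.27 in fibroblast-like cells, in cluster 5 alone the genotype by diet difference of Colec12 reversed to 0.44, and at Leiden resolution 0.5 the unnamed share in E4 control males reversed to 0.29. Leaving out 1 library turned the direction of 7 list results. Their adjusted p over the 16 such fits ranged as follows. In macrophage-like cells of control males ribosome genes ranged from 2.15e-10 to 0.966 and reversed without E4 control male replicate 2, and blood endothelial markers from 1.31e-07 to 0.821, reversed without E3 control male replicate 1. In endothelial-like cells of control males plasma markers ranged from 2.88e-15 to 0.785, reversed without E3 control male replicate 1. In control females oxidative phosphorylation genes of endothelial-like cells ranged from 2.79e-09 to 0.937 and reversed without E4 control female replicate 2. For genotype by sex in macrophage-like cells oxidative phosphorylation genes ranged from 1.31e-08 to 0.762 and ribosome genes from 2.08e-06 to 0.762. Both reversed without E4 control male replicate 2, and ribosome genes also without E3 control male replicate 2. In endothelial-like cells oxidative phosphorylation genes ranged from 3.67e-07 to 0.933 for genotype by sex, reversed without E4 control female replicate 1.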

Other observations

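Apart from the first 5 by rank, the genes named here were chosen only after the result was seen, and the tests were the same as in the report.

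Gata3-led cells, whose clusters were also led by Rnf128 and Arg1, had the largest count of genes between the sexes among the 9 classes tested. On control diet 390 genes passed, 209 higher in males and 181 lower, with 282 by DESeq2. The count ranged from 251 without E3 control female replicate 1 to 513 without E4 control male replicate 1. Neb rose from 10.7 ± 2.78 CPM in females to 78.2 ± 10.6 in males (log2 change 2.81, SE 0.23, adjusted p = 5.4e-12; SD, n = 4). The phospholipase gene Plcb1 rose by 3.22 (SE 0.20), the gut-homing receptor gene Ccr9 by 1.12 (SE 0.12), Klrg1, a receptor of mature innate lymphoid cells, by 1.28 (SE 0.16), Nt5e by 1.35 (SE 0.17), the neuropeptide receptor gene Vipr2 by 1.36 (SE 0.14) and the interleukin-25 receptor gene Il17rb by 0.48 (SE 0.11). The chemokine receptor gene Ccr2 fell by 1.06 (SE 0.11) and Adgrl2 by 1.80 (SE 0.23). Library quality parted the sexes completely on this diet. Between 26.4% and 35.3% of barcodes failed the mitochondrial limit and 256 to 316 the gene limit in the 4 female libraries, against 17.8% to 20.5% and 30 to 82 in the 4 male ones, so sex and preparation cannot be told apart for these genes.

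Glucocorticoid target genes were higher in males in these cells, with 4 of 9 that rose and 5 adjusted over the list alone (adjusted p = 0.017 with an estimated correlation). Fkbp5, a chaperone of the glucocorticoid receptor, rose by 0.94 (SE 0.14), Zbtb16 by 1.37 (SE 0.25), Tsc22d3 by 0.84 (SE 0.24) and Sgk3 by 1.61 (SE 0.48). The same difference in library quality between the sexes applies to them.

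In control females Reln fell in B cell-like cells of E4 mice, from 188 to 49.1 CPM (log2 change -1.94, SE 0.21, adjusted p = 0.0018). It is a lymphatic endothelial marker, and its diet change was -2.38 in E3 females and 1.81 in E4 females.

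In 5 unnamed clusters between 89.6% and 100% of the cells came from E4 PLX5622 female replicate 1, the library with a median of 1329 UMIs per kept cell.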
